A study of Homo sapiens with 9 samples.

How the data were processed

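Total RNA of cultured primary lung fibroblasts was sequenced in 9 libraries, 5 from patients with idiopathic pulmonary fibrosis (IPF) and 4 from healthy controls, per the labels. The series counts as many patients and controls as libraries, so each library was treated as 1 donor. The deposited files hold unscaled counts per Ensembl gene ID, 1 file per library, per the file headers. Per the submitters' processing notes, reads were handled with HISAT2 and HTSeq, and both hg38 and hg19 are named. The roles of these builds, the tool versions, the strand setting, the read filters and the annotation release are not given in the sources used here.

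All values were whole numbers, and library totals ranged from 19942093 to 28288102 with a median of 23442227. Summary lines for unassigned reads were not used here. Of the 58381 gene IDs, 56933 equalled an ID of GENCODE release 29 with its version and 58261 without it, and symbols, biotypes and GRCh38 coordinates were taken from that release. Because the donors are persons, 594 IDs of genes on the Y chromosome, of XIST and its neighbours and of X genes with a Y partner or known escape from X inactivation were left out of every table, which left 57787. Genes with common copy number variation in people were not named. Whether any library duplicated another was checked from the differences between their counts, and no pair lay near sampling noise.

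Genes were tested with edgeR 4.0.16 in R 4.3.3. The steps were filterByExpr on the groups, TMM scaling, robust quasi-likelihood fits with group as the only term, and a two-sided quasi-likelihood F test with Benjamini-Hochberg adjustment over all 16719 genes tested. A gene was called at an adjusted p under 0.05. Standard errors of log2 changes are the size of the change over the square root of F. CPM values use TMM-scaled library sizes. Changes are IPF minus healthy. Principal components were taken from log2 CPM of the tested genes with a prior count of 2. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the remaining tests and the plots.

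Before the data were examined, 25 gene lists and 8 lists of cell type markers were fixed, together with the tests and the rule for naming genes. Of all list members, 1 matched no gene. Lists with at least 5 tested members were tested with camera of limma 3.58.1 on voom values, with a preset correlation of 0.01, two-sided, and adjusted over the gene lists and over the marker lists separately. Camera compares the members of a list with all other genes. Members called higher or lower were counted with the adjustment over all genes and again adjusted over the list alone. The camera calls were repeated with an estimated correlation per list and with fry, which tests whether the genes of a list move one way on balance and makes no comparison with other genes.

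The genes named were the 10 with the most positive and the 10 with the most negative log2 change among called genes with a symbol, a mean log2 CPM of at least 0 and no overlap between the groups. From each list, up to 4 called members with the smallest p were added, or the 2 with the smallest p where none was called. COL1A1, COL3A1, FN1, ACTA2, POSTN and CTHRC1 were always named. This gave 99 names, after some genes that are not reported here were dropped with none taken in their place. Other genes named in the text were chosen after their values were seen and are introduced as such.

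Library measures were total counts, genes with a count, and the shares of mitochondrial genes, of ribosomal protein genes and of the 20 most abundant genes. They were compared by a two-sided exact permutation test over all 126 splits of the 9 libraries into 5 and 4, adjusted over the 5 measures. The smallest p this design allows is 0.00794.

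The fits were tested on simulated data with the means, spread and library sizes of the real libraries. In these, 200 genes were changed 2-fold or 4-fold and a list of 30 more was raised by 0.6 log2. Each gene was drawn independently, without the variation that genes of a real library share, so the rates below may be too favourable. In that run 16365 genes passed the filter. Of the genes that were changed 2-fold and tested, 55.1% of 98 were recovered, and of those changed 4-fold, 82.8% of 93. Beside these, 6 unchanged genes were called, and 0 were called by edgeR when no gene was changed.

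The alternatives fixed in advance were DESeq2 1.42.0, limma voom with quality weights, RLE and upper-quartile scaling, both a looser and a stricter filter on low counts, 1 surrogate variable from sva 3.50.0, the replicate number as a block, autosomal or protein-coding genes alone, a minimum change of 2-fold, and leaving out each library in turn. After the data had been seen, 2 were added: leaving out IPF replicate 2 and healthy replicate 1 together, and removing trends on GC content and exon length from each library. For chance, 100 of the splits of the libraries were drawn with the real one included.

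Without a stated strand setting, reads of genes that overlap on opposite strands cannot be told apart. Of the 99 named genes, 65 overlapped another annotated gene, and 17 of them had a partner with at least 10% of their own counts. These 17 are TOX, TPTEP1, KRT18, TSPAN18, COL4A1, SPINT2, IL6, FZD4, TGFB3, ACVR2A, TYMS, TP53I3, HOXA3, RUNX2, ITGA1, FOSB and ACTA2. Their values are uncertain to a degree that was not measured. For TSPAN18, COL4A1, SPINT2, IL6, FZD4, TGFB3, ACVR2A, HOXA3, ITGA1, FOSB and ACTA2, a partner had more counts than the gene itself. The partner's counts reached 3794% of those of FOSB and 2175% of those of TSPAN18. LCE2A and TPTEP1 belong to families of near-identical copies, among which reads can be divided.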

Results

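The data are gene-level RNA-seq counts of lung fibroblasts, the matrix-producing cells of connective tissue, from people with idiopathic pulmonary fibrosis (IPF, a progressive scarring of the lung) and from healthy people. The cells came from the upper lobe, were grown in medium with 10% serum and were taken at passage 3 or 4. There were 5 IPF libraries and 4 healthy libraries. Counts assigned to genes totalled 23606349, 19942093, 24471725, 22222466 and 28288102 in IPF replicates 1 to 5, and 22941717, 23442227, 23479672 and 21852949 in healthy replicates 1 to 4. The series states 1 question, which genes differ between fibroblasts of IPF patients and of healthy controls. Levels are given as mean ± SD of CPM (counts scaled to library size) over n = 5 IPF and n = 4 healthy libraries. Log2 changes are IPF minus healthy, ± SE, and every adjusted p of a gene is from edgeR's quasi-likelihood test.

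The 5 IPF libraries and the 4 healthy libraries lay on opposite sides of the first principal component, which held 31.1% of the variance, with IPF from −43.0 to −8.35 and healthy from 2.00 to 50.5. Healthy replicate 1 was the healthy library nearest to IPF on this axis, and on the second component (18.8%) it lay at −62.1, with the other libraries from −13.9 to 37.2. Correlations of log2 CPM across genes, which are not independent replicates, had a median of 0.9765 between IPF libraries, 0.9725 between healthy libraries and 0.9617 across the groups. IPF replicate 2 had a count for 41637 genes, against 27142 to 29599 in the other IPF libraries and 27077 to 31200 in the healthy ones. None of the 5 library measures differed past an adjusted p of 0.05 by the exact permutation test, and 1 had an unadjusted p under 0.05. That measure, the share of counts in the 20 most abundant genes, was 12.5% ± 0.647 in IPF and 14.02% ± 0.558 in healthy (exact p = 0.0159, adjusted p = 0.0794). Without healthy replicate 3, this share and that of ribosomal protein genes both passed (adjusted exact p = 0.0446 each).

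**Figure D1:**
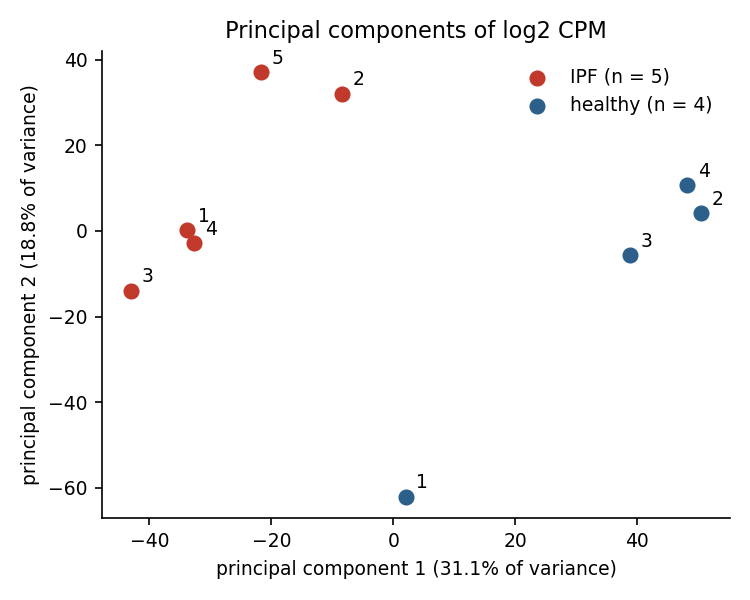
Each point is 1 library, IPF (n = 5) or healthy (n = 4), on the first and second principal components of log2 CPM of the tested genes, with the percent of variance on each axis. The first component separates the groups, and healthy replicate 1 stands apart on the second at −62.1.

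Fibroblasts from IPF lungs had lower levels of the mRNA of several fibrillar and basement membrane collagens than fibroblasts from healthy lungs, and higher levels of several transcription factors of embryonic mesenchyme. COL1A1, a chain of type I collagen, was at 3731 ± 654 CPM in IPF and at 10339.7 ± 777 in healthy. PRRX2, a homeobox transcription factor of embryonic mesenchyme, was at 21.7 ± 4.94 CPM in IPF and at 0.989 ± 0.632 in healthy, a 21.7-fold rise. The decoy receptor BAMBI and the BMP antagonist gene NOG fell, as did the ligand TGFB3, whose gene overlaps another with more counts. FN1 (fibronectin) and ACTA2 (smooth muscle actin of myofibroblasts) were not called.

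Of the 16719 genes tested, 471 passed an adjusted p of 0.05, 176 of them higher and 295 lower in IPF, and 433 of the 471 were protein coding. The median size of their log2 change was 1.37. In 448 of the 471 every IPF library lay on one side of every healthy library. Over all tested genes 6.78% separated the groups in this way, against 1.59% that chance gives. DESeq2 called 1116 genes, which included all 471, and limma voom with quality weights called 1059, which included 445. The count moved when single libraries were left out. It was 835 without healthy replicate 1, 199 without healthy replicate 2, 296 without healthy replicate 3 and 248 without healthy replicate 4. Leaving out an IPF library gave between 331 and 402. In the same order of healthy replicates, 377, 61, 104 and 63 genes were higher and 458, 138, 192 and 185 lower. None of the 471 changed sign in any of these fits. Leaving out 1 library also lowers the power to call genes. A call lost in this way, here or below, need not have rested on that library.

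Among the genes with the largest rises, PRRX2 (ENSG00000167157.10, chromosome 9, 129665641 to 129722674, GRCh38) rose by 4.44 ± 0.40 (adjusted p = 0.00139). CADPS, a regulator of dense-core vesicle release, rose by 4.16 ± 0.59 (adjusted p = 0.00676), and FER1L6, a gene of the ferlin family, by 4.10 ± 0.61 (adjusted p = 0.00742). These 3 were called in all 9 fits that each left out 1 library. The other 7 were SLITRK2, LCE2A, TOX, LRATD1, SLC14A1, KPRP and TPTEP1, with log2 changes between 3.90 and 5.25. They lost their calls without some libraries. TOX, a nuclear factor of the HMG box family, and LRATD1 lost theirs without healthy replicate 2 or 4 (adjusted p up to 0.0787 and 0.0701). The urea transporter SLC14A1 and the keratinocyte gene KPRP did so without healthy replicate 2, 3 or 4 (up to 0.0731 and 0.0781). SLITRK2, a membrane protein of neurons, and LCE2A, of the late cornified envelope family, did so without IPF replicate 1 or healthy replicate 2, 3 or 4 (up to 0.101 and 0.113). For TPTEP1, a pseudogene transcript, the 3 calls that remained were without IPF replicate 3, IPF replicate 5 or healthy replicate 1, and adjusted p reached 0.129 without healthy replicate 2. Leaving out healthy replicate 3 moved the log2 change of TOX from 4.53 to 5.18 and that of LRATD1 from 4.36 to 5.01. That of CADPS was 4.92 without healthy replicate 2, that of SLC14A1 3.34 without IPF replicate 5, and that of SLITRK2 4.55 without IPF replicate 2 and 5.997 without healthy replicate 4.

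Among the largest falls, PDPN, which encodes the membrane glycoprotein podoplanin, was at 0.389 ± 0.233 CPM in IPF and 7.53 ± 4.49 in healthy (log2 change −4.24 ± 0.63, adjusted p = 0.00896). KRT18, a keratin of simple epithelia, fell by 3.95 ± 0.48 (adjusted p = 0.00432), and the tetraspanin gene TSPAN18 fell by 3.85 ± 0.48 (adjusted p = 0.00436). TSPAN18 overlaps TP53I11 on the other strand, which had 2175% of its counts, so its value is uncertain. KIF21B, a kinesin, fell by 3.82 ± 0.66, CDK18, a cyclin-dependent kinase, fell by 3.57 ± 0.57, and GPRC5C, an orphan receptor, fell by 3.44 ± 0.58 (adjusted p = 0.0157, 0.0111 and 0.0144). ITGA11, the alpha-11 chain of a collagen receptor (ENSG00000137809.16, chromosome 15, 68296533 to 68432162), was 11.3 times lower, at 6.19 ± 3.32 CPM against 69.7 ± 16.3 (adjusted p = 0.00169). RSPO3, a secreted enhancer of WNT signalling, was 10.9 times lower, at 8.53 ± 5.91 CPM against 92.6 ± 54.5 (adjusted p = 0.0132). These 8 kept their calls in all 9 fits that left out 1 library. TENM2, a teneurin of cell contacts, lost its call without IPF replicate 2, 4 or 5 or healthy replicate 2 or 3 (adjusted p up to 0.0909), and TMEM233 lost it without healthy replicate 2 (0.0536). The log2 change of TENM2 was −3.89, and −2.98 without healthy replicate 3, and that of TMEM233 −3.47, and −2.83 without healthy replicate 1.

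Of the 25 fixed gene lists, 10 passed camera, 8 of them lower in IPF (collagens, matrix glycoproteins, TGF-beta responsive genes, BMP pathway genes, myofibroblast genes, lipofibroblast genes, unfolded protein response and HOX genes) and 2 higher (developmental transcription factors and interferon-stimulated genes). With an estimated correlation 2 calls held, those of the matrix glycoproteins and of the BMP pathway genes. By fry 7 of the 10 passed, without the myofibroblast, interferon and HOX lists, and the WNT list passed as well. Among 100 splits of the 9 libraries, the real one included, 10 gave at least 10 lists. The others among these each had 4 or 1 IPF libraries in the group of 5 and so kept much of the real contrast. Chance is therefore not excluded for the number of lists, and these splits cannot decide it. Markers of epithelial and of mesothelial cells also passed as lower in IPF, and neither held with an estimated correlation. The median CPM of their members was 1.68 in IPF and 6.48 in healthy for the epithelial list, and 1.69 and 15.6 for the mesothelial list. These markers were thus lower in the same group as the matrix and BMP genes.

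Several chains of fibrillar and basement membrane collagens fell, among them COL1A1, COL3A1, COL5A1 and COL4A1. Of 39 tested genes of collagens and their processing, 11 fell and 3 rose (14 and 4 adjusted over the list alone), with a median log2 change of −0.30 (camera adjusted p = 9.14e-05, adjusted p = 0.175 with an estimated correlation). COL1A1 (ENSG00000108821.13, chromosome 17, 50183289 to 50201632) fell by 1.47 ± 0.15 (adjusted p = 0.00216), 2.77 times. COL3A1, the type III fibrillar chain, fell by 1.68 ± 0.17 from 2225 ± 548 to 696 ± 80.3 CPM (adjusted p = 0.00202). COL5A1, whose chain nucleates collagen fibrils, fell by 1.56 ± 0.14 from 684 ± 91.3 to 231 ± 33.9 CPM (adjusted p = 0.000777), and COL4A1, a basement membrane chain whose gene overlaps COL4A2, by 1.99 ± 0.23 (adjusted p = 0.00335). These 4 kept their calls without any 1 library. The 3 that rose, chosen after their values were seen, were COL10A1, the chain of hypertrophic cartilage, by 1.91 ± 0.34, the procollagen protease ADAMTS14 by 1.65 ± 0.31 and COL7A1, the anchoring fibril chain, by 0.82 ± 0.18. Without healthy replicate 2 none of these 3 was called (adjusted p = 0.05001 for COL10A1, 0.0684 for ADAMTS14 and 0.104 for COL7A1). ADAMTS14 was also lost without healthy replicate 3 or 4, and COL7A1 without IPF replicate 1, 2 or 4 or healthy replicate 1 or 3, so that 1 member was higher without healthy replicate 3.

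Extracellular matrix glycoproteins and proteoglycans included 9 genes of 42 that fell and none that rose (15 and 0 adjusted over the list alone), with a median log2 change of −0.51 (camera adjusted p = 2.93e-05, adjusted p = 0.0357 with an estimated correlation). The fibril-binding proteoglycan FMOD fell by 2.22 ± 0.30 (adjusted p = 0.00607). The laminin chain LAMC1 fell by 1.03 ± 0.16 and LAMA4, another, fell from 1243 ± 316 to 541 ± 101.2 CPM (adjusted p = 0.00896 and 0.0110), and SPARC, a collagen-binding matricellular protein, by 1.06 ± 0.18, from 2594 ± 441 to 1241 ± 253 CPM (adjusted p = 0.0128). FN1 had a log2 change of −0.26 ± 0.22 (adjusted p = 0.662). The number of members that fell was 4 without IPF replicate 2, healthy replicate 2 or healthy replicate 4, and 5 without IPF replicate 4, IPF replicate 5 or healthy replicate 3. Leaving out healthy replicate 1 made 1 member higher and moved the median to −0.31. Genes of matrix degradation did not move as a list (camera adjusted p = 0.527, 1 higher and 2 lower of 29, 2 and 3 adjusted over the list alone). ADAM12, a metalloprotease, fell by 1.78 ± 0.25 (adjusted p = 0.00676). MMP16, a membrane-bound matrix metalloproteinase, rose by 1.60 ± 0.28 but was not called without healthy replicate 4 (adjusted p = 0.0531). TIMP3, an inhibitor of metalloproteinases, was called lower (−1.08 ± 0.24, adjusted p = 0.0413) in the full set and without IPF replicate 5 or healthy replicate 3, and not without any other library (adjusted p up to 0.120). Without healthy replicate 3, 2 members of the list were higher.

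**Figure D2:**
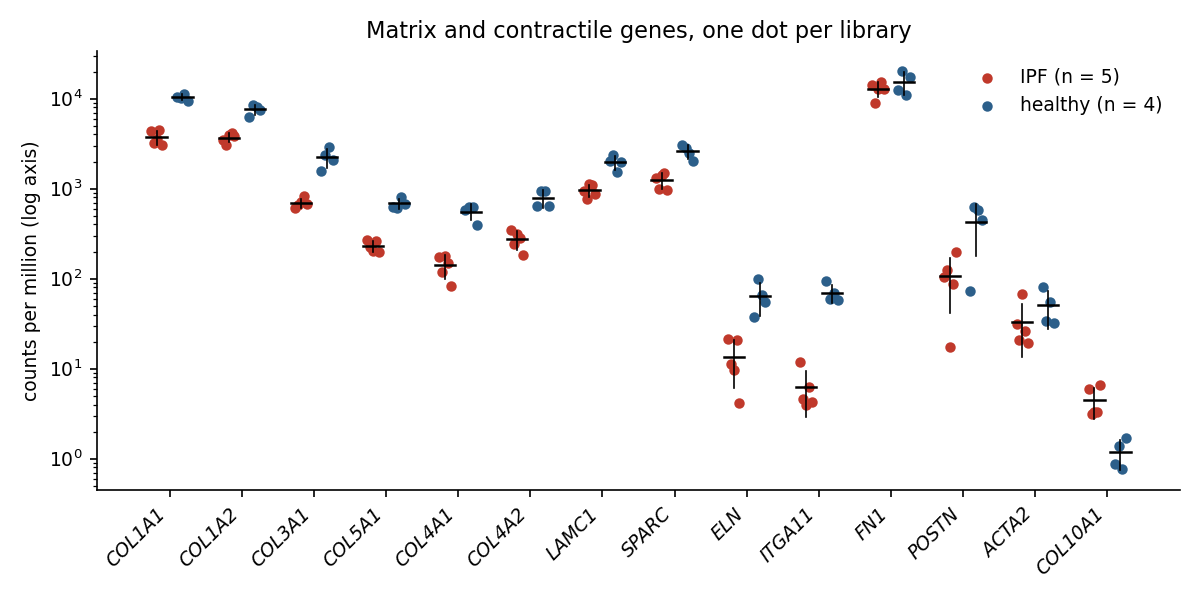
Each dot is the CPM (log axis) of a matrix or contractile gene in 1 library, IPF (n = 5) or healthy (n = 4), with a horizontal bar for the mean and a vertical bar for ± 1 SD. COL1A1 averages 3731 CPM in IPF and 10339.7 in healthy without overlap, while FN1, POSTN and ACTA2 overlap between the groups.

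Genes that respond to TGF-beta, the main profibrotic growth factor, were lower in IPF as a list, with 5 of 25 lower and none higher (7 and 0 adjusted over the list alone) and a median log2 change of −0.48 (camera adjusted p = 1.39e-05, adjusted p = 0.0723 with an estimated correlation). ID2, an inhibitor of basic helix-loop-helix factors, fell by 0.95 ± 0.13 (adjusted p = 0.00662), and SMAD7, which inhibits TGF-beta receptors, by 0.77 ± 0.13 (adjusted p = 0.0117). IGFBP3, a carrier of insulin-like growth factors, was 8.62 times lower, at 99.6 ± 92.4 CPM against 859 ± 507 (adjusted p = 0.0264), and lost its call without IPF replicate 1, IPF replicate 2 or healthy replicate 2 (up to 0.0785). Its log2 change was −3.11, and −3.88 without IPF replicate 3. SKIL, a repressor of SMAD proteins, and ID3, chosen after its value was seen, were called lower in the full set (adjusted p = 0.0393 and 0.0481). SKIL was kept in 1 and ID3 in 2 of the 9 fits that left out 1 library, with adjusted p up to 0.130 for SKIL without healthy replicate 2 and up to 0.114 for ID3 without healthy replicate 3. The lower count was 3 without IPF replicate 1, 3 or 4 or healthy replicate 3 or 4, and 2 without IPF replicate 2 or healthy replicate 2.

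The list of BMP, GDF and activin pathway genes, which also holds the TGF-beta ligands, had 6 of 35 members lower and none higher (12 and 1 adjusted over the list alone), with a median log2 change of −0.56 (camera adjusted p = 1.39e-05, adjusted p = 0.0168 with an estimated correlation). BAMBI (ENSG00000095739.10, chromosome 10, 28677342 to 28682939), a decoy receptor for TGF-beta family ligands, was 5.21 times lower, at 5.06 ± 0.961 CPM against 26.4 ± 6.54 (log2 change −2.38 ± 0.20, adjusted p = 0.000777). NOG, which encodes the BMP antagonist noggin, fell by 2.09 ± 0.35 (adjusted p = 0.0130) and the ligand TGFB3 by 0.94 ± 0.13 (adjusted p = 0.00662). TGFB3 and ACVR2A overlap genes on the other strand with 188% and 231% of their counts, so their values are uncertain. The receptor ACVR2A fell by 0.77 ± 0.13 (adjusted p = 0.0128) but not past the threshold without healthy replicate 2 (adjusted p = 0.0525), where the lower count was 3. Without IPF replicate 3 or healthy replicate 1, 1 member was higher.

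WNT pathway genes did not pass camera as a list (adjusted p = 0.0921, 0 higher and 5 lower of 32, 1 and 7 adjusted over the list alone). They passed as lower by fry (adjusted p = 0.00879), and by camera with the stricter filter on low counts (adjusted p = 0.0451). ROR2, a receptor of WNT5A, fell by 2.49 ± 0.34 (adjusted p = 0.00663), and RSPO3 fell as above. FZD4, a WNT receptor, lost its call without healthy replicate 2 (adjusted p = 0.0510), and DKK1, a secreted WNT inhibitor that fell by 1.32 ± 0.26, lost its call without IPF replicate 1, IPF replicate 2 or healthy replicate 2 (up to 0.0785). The co-receptor LRP5, chosen after its value was seen, fell by 1.29 ± 0.27 and lost its call without IPF replicate 2 or healthy replicate 2, 3 or 4 (up to 0.0953). The lower count was 3 without IPF replicate 2 and 2 without healthy replicate 2, and 2 members were higher without healthy replicate 1. The list passed camera without IPF replicate 3, IPF replicate 5, healthy replicate 3 or healthy replicate 4 (adjusted p from 0.0269 to 0.0497). Growth factors and the IGF axis did not move as a list (camera adjusted p = 0.828, 0 higher and 3 lower of 32, 1 and 3 adjusted over the list alone). Besides IGFBP3, the receptor IGF1R fell by 0.57 ± 0.09 (adjusted p = 0.01002). FGF2, a fibroblast growth factor, fell by 1.01 ± 0.21 (adjusted p = 0.0284) but not past the threshold without IPF replicate 1, 2, 3 or 4 or healthy replicate 2 (up to 0.0975). In this list 1 member was lower without IPF replicate 1, IPF replicate 2 or healthy replicate 2, and 1 and 3 were higher without IPF replicate 4 and healthy replicate 1.

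Transcription factors of lung mesenchyme development were higher in IPF as a list, with 8 of 47 higher and 2 lower (15 and 5 adjusted over the list alone) and a median log2 change of 0.29 (camera adjusted p = 0.00381, adjusted p = 0.106 with an estimated correlation). FOXF1 (ENSG00000103241.6, chromosome 16, 86510527 to 86515418), a forkhead factor of lung mesenchyme, rose 2.33-fold from 53.5 ± 8.42 to 124 ± 16.6 CPM (log2 change 1.22 ± 0.14, adjusted p = 0.00263). RUNX2, a factor of bone formation, rose by 0.74 ± 0.12 (adjusted p = 0.00960). GATA6 (ENSG00000141448.8, chromosome 18, 22169443 to 22202528), a zinc finger factor of lung and heart development, went the other way and was 4.20 times lower, at 4.64 ± 0.928 CPM against 19.5 ± 4.68 (adjusted p = 0.00139). PRRX2, FOXF1, RUNX2 and GATA6 were called in all 9 fits that left out 1 library. The higher count was 3 without healthy replicate 2 or 4 and 4 without healthy replicate 3, and the median was 0.16 without IPF replicate 3 and 0.15 without IPF replicate 4.

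HOX genes, which carry positional identity, were lower as a list, with 15 of 17 log2 changes negative and a median of −0.42 (camera adjusted p = 0.00108, adjusted p = 0.310 with an estimated correlation, fry adjusted p = 0.0874). Only HOXA3, whose annotation overlaps other HOXA genes, was called, with a log2 change of −1.42 ± 0.33 (adjusted p = 0.0494; 0 higher and 1 lower, also adjusted over the list alone). It was called without IPF replicate 5 or healthy replicate 1, where 4 and 3 members were lower, and without any other single library no member was (adjusted p up to 0.136 for HOXA3). The median was −0.26 without IPF replicate 3.

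**Figure D3:**
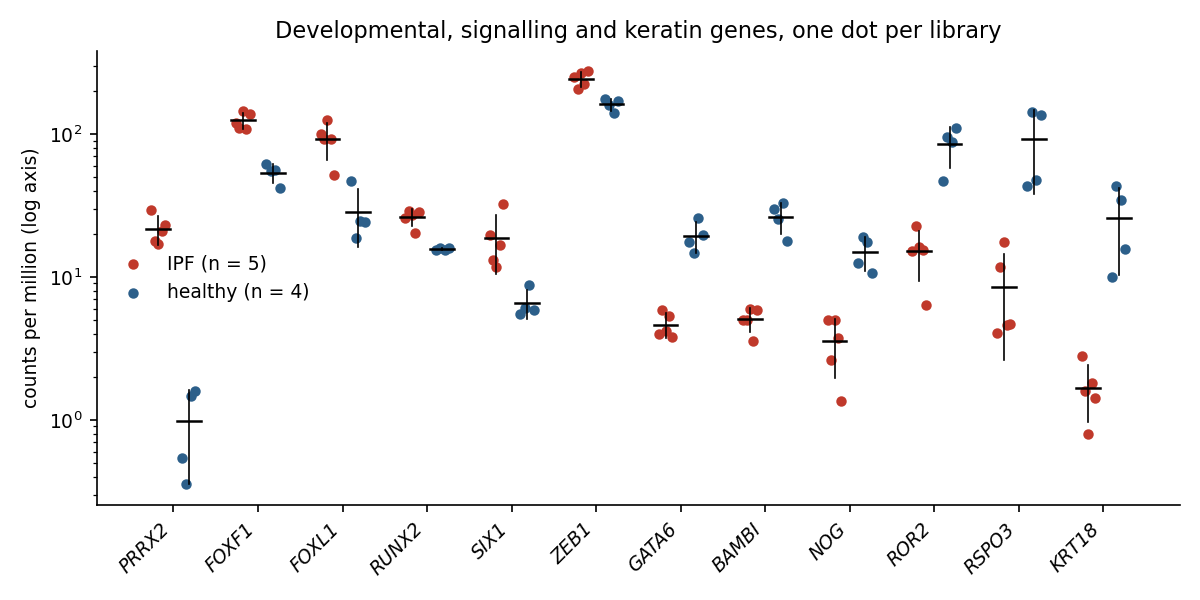
Each dot is the CPM (log axis) of a transcription factor, signalling or keratin gene in 1 library, IPF (n = 5) or healthy (n = 4), with a horizontal bar for the mean and a vertical bar for ± 1 SD. PRRX2 averages 21.7 CPM in IPF and 0.989 in healthy, FOXF1 124 and 53.5, BAMBI 5.06 and 26.4, and KRT18 1.68 and 26.0.

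Contractile and myofibroblast genes were lower in IPF as a list, with 2 of 24 lower and none higher (6 and 1 adjusted over the list alone) and a median log2 change of −0.31 (camera adjusted p = 0.000760, adjusted p = 0.461 with an estimated correlation, fry adjusted p = 0.112). The members called were ITGA11 and TPM1, a tropomyosin, which fell by 0.87 ± 0.15 (adjusted p = 0.0128). ACTA2 was at 33.0 ± 19.6 CPM in IPF and 50.5 ± 22.7 in healthy (adjusted p = 0.549). POSTN (periostin) had a log2 change of −2.01 ± 0.67 and CTHRC1, a marker of activated fibroblasts, of −0.12 ± 0.31 (adjusted p = 0.181 and 0.915). POSTN was called lower without healthy replicate 1 (log2 change −2.34, adjusted p = 0.0396) and with 1 surrogate variable (−1.86, 0.0283), but not in the other 8 fits that left out 1 library. Without healthy replicate 1 the list did not pass (camera adjusted p = 0.0545), 2 members were then higher, and the median was −0.19.

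Genes of lipofibroblasts and alveolar fibroblasts were lower as a list, with 3 of 17 lower and none higher (6 and 1 adjusted over the list alone) and a median log2 change of −0.50 (camera adjusted p = 0.0155, adjusted p = 0.175 with an estimated correlation). LIMCH1, an actin-binding protein, fell by 2.06 ± 0.15 (adjusted p = 0.000428) from 102 ± 17.4 to 24.5 ± 4.24 CPM. MACF1, a microtubule and actin crosslinker, fell by 0.93 ± 0.17 and SPINT2, a serine protease inhibitor, by 2.74 ± 0.52. Without healthy replicate 2 only LIMCH1 was called (adjusted p = 0.05001 for MACF1 and 0.0769 for SPINT2), SPINT2 was also lost without IPF replicate 2, and the list did not pass without IPF replicate 1 (camera adjusted p = 0.110). The fit without healthy replicate 1 had 1 member higher and a median of −0.12, and that without healthy replicate 2 a median of −0.28. Adventitial fibroblast genes did not move as a list (camera adjusted p = 0.618, 1 higher and 3 lower of 13, 3 and 4 adjusted over the list alone), and their median log2 change was 0.09, their mean −0.25 and the direction of the test down. The median was negative without IPF replicate 4 or 5 or any 1 healthy library (down to −0.36 without IPF replicate 5). CLU, a secreted chaperone, rose by 1.81 ± 0.27 (adjusted p = 0.00935). The matrix protein gene CCDC80 fell by 1.11 ± 0.17 and the surface peptidase gene DPP4 by 2.08 ± 0.34 (adjusted p = 0.00750 and 0.0132). PTGDS, a prostaglandin synthase, was called lower in the full set (adjusted p = 0.0414), and of the 9 fits that left out 1 library only in that without healthy replicate 1 (up to 0.134 in the others). In that fit 3 members were higher.

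Genes of the unfolded protein response and secretory pathway were lower by small amounts, with 26 of 28 log2 changes negative and a median of −0.27 (camera adjusted p = 2.41e-05, adjusted p = 0.175 with an estimated correlation). HERPUD1, of endoplasmic reticulum degradation, was the member called (log2 change −0.47 ± 0.09, adjusted p = 0.0237; 0 higher and 1 lower, also adjusted over the list alone), and it was not called without IPF replicate 4 or healthy replicate 2 or 3 (up to 0.0779). Interferon-stimulated genes were higher as a list, with 24 of 28 log2 changes positive and a median of 0.30 (camera adjusted p = 0.00221, adjusted p = 0.427 with an estimated correlation, fry adjusted p = 0.2097). USP18, an inhibitor of interferon signalling, was the member called, with a log2 change of 1.25 ± 0.27 (adjusted p = 0.0345; 1 higher and 0 lower, 2 and 1 adjusted over the list alone). Without IPF replicate 5 the list did not pass (camera adjusted p = 0.102) and its median was 0.16. USP18 was called without IPF replicate 4 or healthy replicate 1, where 2 members were higher, and lost its call without any other library (up to 0.0960).

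Inflammatory cytokines, chemokines and NF-kB targets did not move as a list (camera adjusted p = 0.527, 1 higher and 3 lower of 25, 6 and 6 adjusted over the list alone). The adhesion receptor ICAM1 fell by 2.02 ± 0.33 (adjusted p = 0.0130) and the alarmin IL33 by 2.81 ± 0.49 (adjusted p = 0.0156; log2 change −2.13 without healthy replicate 2). The cytokine gene IL6 fell by 1.48 ± 0.28 (adjusted p = 0.0212) and lost its call without healthy replicate 2 or 3 (up to 0.0667). TNFAIP2 rose by 0.90 ± 0.19 (adjusted p = 0.0294) and lost its call without IPF replicate 2 or 5 or healthy replicate 2 or 3 (up to 0.0930).

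Cell adhesion and integrin genes moved both ways (camera adjusted p = 0.542, 2 higher and 3 lower of 35, 4 and 8 adjusted over the list alone). The cadherin genes CDH2 and PCDH7 fell by 1.29 ± 0.19 and 2.08 ± 0.37 (adjusted p = 0.00676 and 0.0176), and the tetraspanin CD9 rose by 1.18 ± 0.23 (adjusted p = 0.0254). The integrin chain ITGA1 fell by 0.72 ± 0.15 and ITGA10, chosen after its value was seen, rose by 2.92 ± 0.61 (adjusted p = 0.0305 and 0.0338). PCDH7 lost its call without healthy replicate 2 or 4 (up to 0.0537) and CD9 without IPF replicate 1 or healthy replicate 2 or 4 (up to 0.0830). ITGA1 lost its call without IPF replicate 2, 4 or 5 or healthy replicate 2 or 3 (up to 0.122), and ITGA10 without IPF replicate 1 or 2 or healthy replicate 2, 3 or 4 (up to 0.118). The log2 change of ITGA10 was 2.297 without IPF replicate 5. There were 5 lower members without healthy replicate 1, and without healthy replicate 2, 1 was. None was higher without IPF replicate 1 or healthy replicate 4, and 1 was without IPF replicate 2 or healthy replicate 2 or 3.

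Prostaglandin, ion channel and receptor genes did not pass as a list (camera adjusted p = 0.641, 4 higher and 2 lower of 35, 8 and 8 adjusted over the list alone). TRPA1, an irritant-gated cation channel, rose 9.06-fold from 16.7 ± 5.56 to 151 ± 90.9 CPM (log2 change 3.18 ± 0.51, adjusted p = 0.0129) and was called in all 9 fits that left out 1 library. The prostaglandin F receptor gene PTGFR rose by 1.03 ± 0.21 (adjusted p = 0.0264) and was kept without IPF replicate 1, IPF replicate 3 or healthy replicate 1 alone (up to 0.0902 without the others). PTGDS is a member as well. PTGER2, a prostaglandin E receptor chosen after its value was seen, and ADRA1B, the alpha-1B adrenergic receptor, had adjusted p of 0.04995 (higher) and 0.0385 (lower), and each was kept in 2 of the 9 fits (up to 0.144 without healthy replicate 2 and 0.0967 without healthy replicate 3). The higher count was 2 without IPF replicate 2, 4 or 5 and 1 without healthy replicate 2, 3 or 4. The lower count was 0 without IPF replicate 1, 2, 3 or 4 or healthy replicate 3, and 1 without IPF replicate 5 or healthy replicate 2 or 4.

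Several processes showed no call as a list in the full set and no gene called by edgeR. No cell cycle gene of 35 was called (camera adjusted p = 0.119, 0 adjusted over the list alone), 1 had an unadjusted p under 0.05 and 0 were called by DESeq2 or voom, with PCNA at 0.27 ± 0.12 and TYMS at 0.32 ± 0.19 (adjusted p = 0.331 and 0.473). This list passed as higher without IPF replicate 3, IPF replicate 5, healthy replicate 3 or healthy replicate 4 (camera adjusted p from 0.00484 to 0.0108). Among 26 senescence and p53 target genes none was called (camera adjusted p = 0.816, 0 adjusted over the list alone, 3 at an unadjusted p under 0.05, 0 by DESeq2 or voom), and FDXR and TP53I3 both had a log2 change of 0.38 (adjusted p = 0.156 and 0.285). Without healthy replicate 1 or 3, 1 of these genes was higher. None of 28 hypoxia and glycolysis genes was called (camera adjusted p = 0.0935, 1 higher and 3 lower adjusted over the list alone, 9 at an unadjusted p under 0.05, 4 by DESeq2 and 3 by voom), with PFKFB4 at 0.64 ± 0.15 and KDM3A at −0.48 ± 0.12 (adjusted p = 0.0528 and 0.0563). That list passed as lower without IPF replicate 3, healthy replicate 2 or healthy replicate 4 (camera adjusted p = 0.0110, 0.0144 and 0.0414). None of 29 cholesterol and lipid genes was called (camera adjusted p = 0.3202, 0 adjusted over the list alone, 2 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by voom), with a median log2 change of 0.01 (−0.07 without healthy replicate 1 to 0.19 without healthy replicate 3), a mean of −0.05 and an upward test. FDPS, of the mevalonate pathway, was at 0.33 ± 0.15 (adjusted p = 0.321), and the list passed as higher without healthy replicate 3 (camera adjusted p = 0.00328). None of 39 chromatin regulators was called (camera adjusted p = 0.108, 0 adjusted over the list alone, 7 at an unadjusted p under 0.05, 2 by DESeq2 and 2 by voom), with the demethylase genes KDM5B at −0.34 ± 0.08 and KDM6B at −0.35 ± 0.12 (adjusted p = 0.0570 and 0.165). They passed as lower without healthy replicate 1 (camera adjusted p = 0.0430). None of 21 immediate early and heat shock genes was called (camera adjusted p = 0.773, 0 adjusted over the list alone, 5 at an unadjusted p under 0.05, 0 by DESeq2 and 2 by voom), with FOSB at −0.90 ± 0.29 and FOSL1 at 0.44 ± 0.15 (adjusted p = 0.149 and 0.176). In the fit without healthy replicate 1, 1 gene was called higher in the hypoxia and in the immediate early list and 1 lower in the hypoxia, cholesterol and chromatin lists. The same number was higher without IPF replicate 1 in the immediate early list and without healthy replicate 3 in the hypoxia list, and lower without IPF replicate 4 in the chromatin list. Of the genes named here, KDM3A and KDM6B were called lower and FOSL1 higher without healthy replicate 1 (adjusted p = 0.0189, 0.0486 and 0.0225), and FDXR and PFKFB4 higher without healthy replicate 3 (0.0434 and 0.0421).

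In the NRF2 and oxidative stress list (camera adjusted p = 0.286) 1 of 30 members was called, also adjusted over the list alone. It was CAT, which encodes catalase, with a rise of 0.53 ± 0.11 (adjusted p = 0.0264), and it was lost without IPF replicate 5 or healthy replicate 2, 3 or 4 (up to 0.0814). Genes near common or rare variants linked to pulmonary fibrosis had 1 higher and 1 lower of 20 (camera adjusted p = 0.773, 2 and 1 adjusted over the list alone), with a median log2 change of −0.03 (up to 0.06 without healthy replicate 4), a mean of −0.12 and an upward test. ABCA3, a lipid transporter, rose by 1.73 ± 0.39 and DEPTOR, an mTOR inhibitor, fell by 1.82 ± 0.38 (adjusted p = 0.0471 and 0.0301). ABCA3 was kept without IPF replicate 1 or 4 and DEPTOR without IPF replicate 5, healthy replicate 1 or healthy replicate 2, with adjusted p up to 0.112 and 0.0914 without the others.

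**Figure D4:**
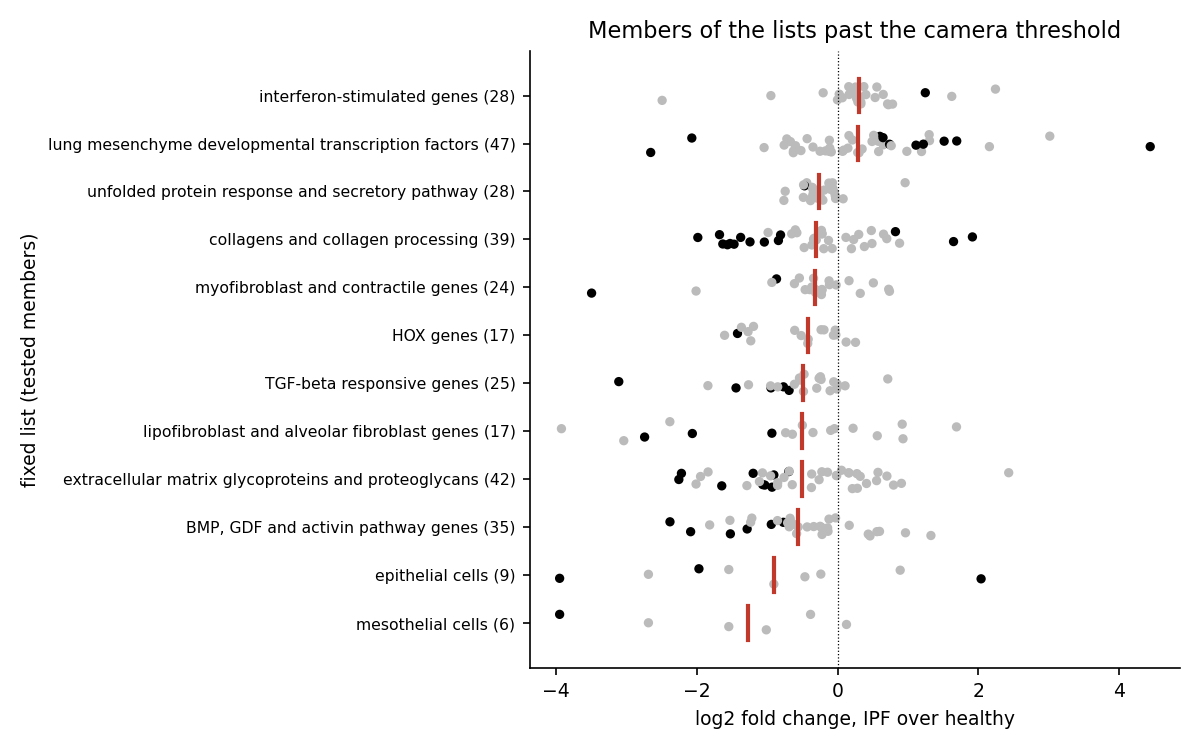
Each dot is the log2 change (IPF over healthy) of a tested member of a list that passed camera, black where the gene itself was called and grey where it was not, and red bars are medians. The medians run from −1.28 for mesothelial markers to 0.30 for interferon-stimulated genes, and most members of most lists are grey.

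Markers of other cell types were mostly at low levels. Epithelial markers were lower in IPF as a list (camera adjusted p = 0.0108, adjusted p = 0.154 with an estimated correlation), with 2 of 9 lower and 1 higher (4 and 1 adjusted over the list alone). Mesothelial markers were lower as well (camera adjusted p = 0.00284, adjusted p = 0.154 with an estimated correlation), with 1 of 6 lower (4 and 0 adjusted over the list alone), and 2 lower without IPF replicate 3 or healthy replicate 1. The mesothelial list shares KRT8, KRT18 and KRT19 with the epithelial one. KRT18 (ENSG00000111057.10, chromosome 12, 52948871 to 52952901) was at 1.68 ± 0.720 CPM in IPF and 26.0 ± 15.7 in healthy, and its annotation overlaps that of KRT8. KRT19 was at 35.9 ± 14.6 and 105 ± 35.9 CPM (adjusted p = 0.0722). The number of epithelial markers called lower was 1 without healthy replicate 2, 3 or 4. KRT17 rose by 2.04 ± 0.35 (adjusted p = 0.0134) at 0.532 ± 0.117 against 0.126 ± 0.0271 CPM, and without IPF replicate 1, 2, 4 or 5 it did not reach the minimum for testing. Among 100 splits of the libraries, 10 gave at least 2 marker lists, the real one included.

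Endothelial markers did not move as a list (camera adjusted p = 0.747, 0 of 6 called by edgeR, 0 adjusted over the list alone, 1 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by voom), with a median log2 change of −0.05 (−0.20 without IPF replicate 5 to 0.32 without healthy replicate 2), a mean of −0.13 and an upward test, and VWF and ROBO4 at 0.94 ± 0.39 and 0.56 ± 0.26 (adjusted p = 0.278 and 0.348). Of the smooth muscle and pericyte markers (camera adjusted p = 0.213), 1 of 12 was higher (2 adjusted over the list alone). It was SYNM, an intermediate filament protein, with a rise of 1.06 ± 0.19 (adjusted p = 0.0172) that was lost without healthy replicate 2 or 4 (up to 0.0621). Cartilage and bone markers (camera adjusted p = 0.213) had 1 higher and 1 lower of 8 (2 and 1 adjusted over the list alone). SPP1 (osteopontin) fell by 2.39 ± 0.41 (adjusted p = 0.0145) and lost its call without healthy replicate 2 (0.0526). SOX9, a factor of cartilage formation, rose by 0.65 ± 0.13 (adjusted p = 0.0242) and lost its call without IPF replicate 1 or 4 or healthy replicate 2, 3 or 4 (up to 0.0773). None of 7 Schwann and neural markers was called (camera adjusted p = 0.293, 0 adjusted over the list alone, 2 at an unadjusted p under 0.05, 1 by DESeq2 and 1 by voom), with GAP43 at 1.72 ± 0.54 and SYT1 at 0.94 ± 0.37 (adjusted p = 0.140 and 0.267). Leukocyte and adipocyte markers had 3 tested members each, too few for the list test, and none was called (0 and 2 adjusted over the list alone, 0 and 2 at an unadjusted p under 0.05, 0 and 2 by DESeq2 and by voom). In the fit without healthy replicate 1, 1 adipocyte, 1 neural and 2 smooth muscle markers were higher, without IPF replicate 3, 1 neural, and without healthy replicate 3, 1 adipocyte marker. CD14 and LAPTM5 were at −0.31 ± 0.31 and 0.64 ± 1.00 (adjusted p = 0.724 and 0.845, and LAPTM5 at −1.48 without IPF replicate 4), and FABP4 and LEP at 2.35 ± 0.64 and 2.12 ± 0.62 (adjusted p = 0.0874 and 0.107). FABP4 and SYT1 were called higher without healthy replicate 1 (3.38 and 1.51, adjusted p = 0.0112 and 0.0116), LEP without healthy replicate 3 (3.07, adjusted p = 0.0445) and GAP43 without IPF replicate 3 (adjusted p = 0.0184).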

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

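The tests of GC content and length, of the share of fibroblasts, of the keratin ratio and of sequencing depth were chosen after the results they bear on had been seen, and the bound of the keratin test was made stricter after its first value. In each group, a library was singled out where its gap to the nearest other library of the group was large against the range of that group, for 208 groups formed by the library measures and the named genes. For normally distributed values, chance singles out a library in about 1 in 20 groups. CPM values need not be normal and the groups share the same 9 libraries, so the chance rate here is not known. There were 17 such cases in the 208, 5 of them in healthy replicate 1 and 4 in IPF replicate 3, and no excess is read from this.

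Among IPF libraries, ITGA11 was at 11.92 CPM in IPF replicate 1 (others 3.951 to 6.193). IPF replicate 2 had ACVR2A at 9.986 CPM (others 7.559 to 8.258) and VWF at 2.576 (others 1.16 to 1.366). IPF replicate 3 had IGFBP3 at 264.1 CPM (others 44.28 to 67.53), DPP4 at 176.2 (others 56.81 to 85.51), LEP at 2.648 (others 0.6825 to 1.047) and ACTA2 at 67.0 (others 19.14 to 31.63). IPF replicate 4 had FZD4 at 87.38 CPM (others 52.46 to 62.29), PCDH7 at 62.61 (others 20.47 to 28.33) and LAPTM5 at 6.193 (others 0.1261 to 0.5119).

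Among healthy libraries, replicate 1 had ADAM12 at 79.46 CPM (others 150.4 to 158.8), PTGDS at 1.13 (others 4.825 to 4.918), IGF1R at 163.1 (others 179.5 to 181.5), SYNM at 5.013 (others 4.281 to 4.338) and SYT1 at 13.46 (others 4.138 to 5.312). Healthy replicate 3 had LEP at 0.6466 CPM (others 0.1328 to 0.1474).

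The number of genes with a count was 41637 in IPF replicate 2 and 27142 to 29599 in the other IPF libraries. Depth is argued against, because after thinning every library to 19857634 counts it still had 11400 genes more than any other (26328 to 30237). RNA of another cell type was not settled. The 7052 genes seen in this library alone held 17768 counts, with 1.79% of them in the 10 most abundant, under the bound set against it. Only genes without a count in any other library entered, so abundant transcripts with a stray count elsewhere could not show. The share also tends to fall as more genes enter, and was 3.951% over 713 such genes in healthy replicate 3. Reads spread over the genome, such as those of DNA, could not be decided. The variance of counts of genes silent in the other libraries, around a rate per exon base, was 3.281 times the Poisson variance. This lay between the bounds set for and against. Counts were seen for 264 of 388 olfactory receptor genes, against 28 to 108 in the other libraries. No biological explanation was tested.

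The 11 genes called lower in the list of collagens and collagen processing, among them enzymes and a chaperone beside the collagen chains, had a median log2 change of −1.47. A distortion by abundance is argued against, because 169 genes matched to them in abundance had a median of −0.009969 (SD 0.258). Of the matched genes 0% lay at or below the median of the 11, which had been picked as called lower. An error of library scaling could not be tested in this way, because TMM scaling itself places the bulk of genes near no change. Trends on GC content and length are argued against as the whole cause, since 11 members of the list were also called lower once these were removed. Whether each was the same gene was not checked. The median of the whole list moved from −0.3026 to −0.2345. A lower share of fibroblasts in the IPF cultures is argued against as the whole cause only for a loss to cells that lack the fibroblast genes tested. Cells that carry these genes as well, which include VIM, CD44, THY1 and PDGFRA, could take the place of fibroblasts without showing here. For this, 20 genes that fibroblasts of all kinds express had a median of −0.06848 (SD 0.680), with 9 above 0. Any of the 11 were left out of these 20 beforehand, so they describe the other fibroblast genes only. The disease and other differences between donors, passage and culture stay open as untested, and since these values were found and tested on the same data, a change in the cells may be read from them only as a hypothesis.

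KRT18 was called lower in IPF and KRT19, at 35.9 CPM in IPF and 105 in healthy, was not (edgeR adjusted p = 0.0722), and cells of another type that carry both in a fixed ratio were tested as a source. The lowest ratio of KRT19 to KRT18 excess that the spread of the IPF libraries allows in healthy replicate 1 (11.48) was 6.453 times the highest allowed in healthy replicate 3 (1.779), but without healthy replicate 1 this value was 1.657, under the bound of 2 set for the test, so it rests on 1 library. In unscaled CPM, the epithelial markers EPCAM (0.714 in healthy, 0.650 in IPF) and CDH1 (0.140, 0.248) and the mesothelial markers MSLN (0.0222, 0.129) and UPK3B (0.0109, 0.0276) stayed near the floor, and KRT7 was not higher in healthy (10.7, 21.7), which goes against cells that carry these markers. The mesothelial marker BNC1 (26.2, 13.8) and the epithelial marker CLDN4 (6.22, 3.56) went the other way, and no bound on these markers was set before they were seen. Cells that lack the low markers and keratin expression in fibroblasts themselves cannot be told apart here, because the ratio rests on 1 library and reads of KRT18 and KRT8 overlap, and a difference of the disease or the donors stays open as untested.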

How the results depend on the processing

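Removing trends on GC content and length, and leaving out IPF replicate 2 and healthy replicate 1 together, were chosen after seeing the data. The number of genes called differed between settings and with single healthy libraries. DESeq2 was run on 45963 genes against 16719, voom also weighted the libraries and edgeR on 46103 genes called 527, so no difference between the tools alone was measured. Against 471 genes (176 higher, 295 lower), DESeq2 called 1116 (509 and 607), limma voom with quality weights 1059 (464 and 595) and the fit with 1 surrogate variable 790 (319 and 471). Leaving out both libraries gave 691, of which 302 were higher, and a minimum change of 2-fold gave 312, with 114 higher. Leaving out 1 library gave 199 (without healthy replicate 2) to 835 (without healthy replicate 1) genes, 61 to 377 of them higher and 138 to 458 lower. Other scalings, filters, gene sets and the GC and length trends gave 448 to 527. No called gene changed sign under any setting. The median log2 change of all genes moved to 0.150 with DESeq2 and to 0.155 with every gene that had a count, both over many more weakly expressed genes.

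Of the 76 named genes past the threshold, 39 were past it in all 9 fits that left out 1 library and 62 in at least 5. With an estimated correlation, 2 gene lists and 0 marker lists passed in place of 10 and 2, and fry called 8 and 2, the 8 being 7 of the 10 and the WNT list. Leaving out 1 library gave 9 to 13 gene lists. Library measures past the threshold numbered 0 to 2, with 2 without healthy replicate 3 (exact permutation test). In the fits that left out 1 library, 1 measure alone could not pass. The smallest two-sided exact p was 0.0286 without an IPF library (adjusted p = 0.143 for 1 measure) and 0.0179 without a healthy one (0.0893). The share of the 20 most abundant genes was at this limit without each IPF library, so a count of 0 there shows no stability. For single genes, 1338 values under other settings kept their side of the threshold, 31 passed it and 209 lost it. For lists these were 524, 16 and 18, and 0 were reversed.

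With the replicate number as a block, over the libraries numbered 1 to 4, 144 genes were called, 50 higher and 94 lower, and 119 of them were among the 471. Of the 76 named genes past the threshold, 26 were past it in this fit. This fit also has 1 library less. The numbers did not pair the libraries: deviations from the group means correlated at 0.041, 0.229, −0.022 and −0.231 for numbers 1 to 4, and not every library correlated best with its own number. With the block the interferon list did not pass (camera adjusted p = 0.0891) and the cell cycle list did (0.0280), and no other list call changed.

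At these depths 55.1% of 2-fold changes were recovered in simulated data, so genes not called are not shown to be equal.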

Other observations

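The tests of HOXA against HOXB genes and of neighbouring genes were chosen after the values were seen, as were the bound against the HOXA hypothesis and the genes of the next paragraphs. The teneurin TENM3 was at 21.8 ± 9.12 CPM in IPF (mean ± SD, n = 5) and 136 ± 36.1 in healthy (n = 4; log2 change −2.64 ± 0.33, edgeR adjusted p = 0.00525). NEO1, a receptor of netrins and repulsive guidance molecules, fell from 195 ± 7.84 to 69.5 ± 18.3 CPM (edgeR adjusted p = 0.00513). PLXDC2, a plexin domain protein, fell from 58.3 ± 1.66 to 20.6 ± 2.03 CPM (edgeR adjusted p = 0.000111), and the semaphorin receptor PLXND1 fell by 0.82 ± 0.11, while another, PLXNB3, rose by 1.27 ± 0.21. These 5 were called without any 1 library. PLXNA4 rose by 1.502 ± 0.26 but was not called without healthy replicate 2 or 3 (adjusted p up to 0.0527). The netrin receptor UNC5C was called lower (adjusted p = 0.0342) in the full set and not without IPF replicate 1, 2 or 3 or healthy replicate 2, 3 or 4 (up to 0.0914).

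Outside the fixed lists, CEMIP, which takes part in hyaluronan breakdown, was at 178 ± 55.8 CPM in IPF and 1346 ± 706 in healthy (log2 change −2.91 ± 0.35, edgeR adjusted p = 0.00421). FRAS1, a matrix protein of embryonic basement membranes, fell by 3.37 ± 0.44, and PAPPA, a protease of IGF binding proteins, fell by 1.93 ± 0.20. LTBP1, which binds latent TGF-beta in the matrix, rose from 269 ± 68.7 to 604 ± 133 CPM (edgeR adjusted p = 0.0136). FENDRR, a long noncoding RNA whose gene lies beside FOXF1 without overlap, rose from 4.89 ± 1.41 to 38.4 ± 14.2 CPM (edgeR adjusted p = 0.00259). MAOB, a monoamine oxidase, rose by 1.53 ± 0.21, and SCARA3, a scavenger receptor, rose by 1.55 ± 0.26. All 7 were called without any 1 library. GPNMB, a membrane glycoprotein, rose by 1.81 ± 0.38 and lost its call without IPF replicate 3 or healthy replicate 2, 3 or 4 (up to 0.104).

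The 471 genes called stood apart from other splits of the libraries: of 100 splits of the 9 libraries into 5 and 4, 1 gave as many, the real one, and the highest other gave 18. That is the smallest share these splits can give. Every other split also mixes the groups, which widens the spread within them and lowers the count. Differences between donors that coincide with the groups were not addressed. For the number of lists, chance cannot be excluded. The real 10 gene lists were reached or passed in 10 of 100 splits, with 12 in the highest other, and the real 2 marker lists in 10 of 100, with 2 in the highest other. For the gene lists, the other splits that did so had 4 or 1 IPF libraries in the group of 5. Those drawn with 2 or 3 gave at most 9 gene lists. A split that keeps much of the real contrast is no clean measure of chance, so the gene list count stays undecided.

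A hypothesis was that the lower HOX values lie in the HOXA cluster. The 7 tested HOXA genes had a median log2 change of −1.27 and the 7 HOXB genes −0.0595, and the difference of their mean log2 CPM was −0.519 between the groups (two-sided exact permutation p = 0.03968). The contrast was picked from these same values, so this p lends the hypothesis no weight. HOXA3 was the only one of these genes called by edgeR, and reads of overlapping HOXA genes cannot be separated. Differences in the site of sampling within the lobe, the donors and the disease stay open as untested.

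A second hypothesis was that genes next to each other on a chromosome change together. Of 5000 adjacent pairs of tested genes on 1 strand, without overlap and within 100000 bases, 7 had both genes called in the same direction, against a mean of 2.07 and a highest of 10 over 10000 shuffles of the calls (permutation p = 0.005), and 1 pair was called in opposite directions. The pairs include LCE2A with KPRP, MAOB with NDP and ANKRD35 with ITGA10, and the last lie 5342 bases apart. The pairs were noticed in the same calls, so this p leaves the hypothesis open. It may reflect shared regulation, or reads that run past the end of 1 gene into the next, which was not tested. NDP alone rose by 3.22 ± 0.55 (edgeR adjusted p = 0.0136) and was not called without healthy replicate 2 (0.0537).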
